A study of Homo sapiens with 16 samples.

How the data were processed

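H3K27me3 and H3K4me3 were profiled by ChIPmentation in TKO cells expressing wild type NSD2, D1240A or F1295A, and in plain TKO cells. Cells were fixed in formaldehyde at 0.8%, and glycine at 0.125 mol/L stopped the reaction, per the labels' protocols. The 16 samples formed 12 groups of form and antibody, with 2 H3K27me3 samples, 1 H3K4me3 sample and 1 IgG sample per form. The IgG samples were not analysed here.

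The deposited data were 8 peak lists. Trimmomatic 0.36, FastQC 0.11.4, Bowtie2 2.4.5, SEACR 1.3 and the build GRCh38 are named in the submitters' processing notes, and the mode, control and threshold of peak calling are not given in the sources used here. Per the labels, both H3K27me3 samples of a form point to the same list. In each peak the deposited lists give the total signal and the highest signal (coverage) as the authors' peak caller wrote them, and any scaling is not given. Highest signal in the H3K27me3 lists moved in steps of 0.5, whereas the H3K4me3 lists held whole numbers. At most 0.0170% of H3K27me3 totals per list were whole, with values such as 539.317. Averaging of whole-number replicates alone would not give such totals, so how the replicates were combined is unknown. Signal was therefore used mainly to rank, filter or describe peaks within a list. Between lists, the lowest mean signal of each list was set side by side as a description, and H3K4me3 signal on part of chromosome 1 was compared only relative to peaks elsewhere in the same list. The lists hold no read totals, so the depth of each sample is unknown, and a longer list can come from a deeper sample or a looser threshold. No value of a single H3K27me3 replicate could be compared, so no test between forms was run and no p-values are given.

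Peak lists were compared by the number of peaks, by covered bases and by overlap of at least 1 bp, computed in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, with figures from matplotlib 3.10.9. Overlap was set beside the mean of 100 circular shifts, along each chromosome, of the list whose share was counted. Shares have Clopper-Pearson 95% intervals, and ratios of peak numbers have 95% intervals from the same binomial method. These cover counting error only.

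Gene records came from a RefSeq table of GRCh38.p14 that gives no strand, so a promoter was read as the 1 kb around either end of a protein-coding gene record on chromosomes 1 to 22 and X. This gave 19974 genes, of which 10946 were marked in at least 1 list. The planned test used the transcription start site, and both gene ends took its place. For each pair of forms, genes marked in a single form were counted. The 17 gene lists, the 14 genes always reported, the pairs, the alternatives other than those said below to be added later, and the naming rule were fixed before the data were examined. The lists covered cadherins, clustered and non-clustered protocadherins, integrins, immunoglobulin-type adhesion molecules, extracellular matrix, migration receptors, t(4;14) genes, plasma cell, B cell, HOX, developmental factor, cell cycle, Polycomb, housekeeping, T, NK and myeloid, and stromal genes. Of their 622 entries, 619 matched the gene table. Each count was placed among 10000 random lists of equal size drawn with fixed seeds and matched on 10 groups of gene length, and, for genes marked in a single form, also among random draws from the genes marked in that form. In all, 272 list comparisons between forms were computed, of which 16 lay above the middle 95% of random lists and 0 below it. In most comparisons a count of 0 was itself inside the middle 95%, so these could not lie below it. A random list that ties with a count is split evenly above and below it. Promoter CpG content was not matched, since no genome sequence was at hand. All percentiles describe these libraries and are not p-values.

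Genes were named by rule. For each pair, mark and direction, the rule took from every list up to 4 members that were marked in a single form and had no peak of that mark within 10 kb of a gene end in the other, in order of marked bases within 10 kb, and the 8 such genes with the most marked bases among all protein-coding genes. The rule also took 4 genes without a proper symbol, which are left out of the text. Some other genes that the rule or the lists name are not reported here. Where a kb value follows a gene name, it is the marked length within 10 kb of the gene ends in the form that has the mark.

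The alternatives joined peaks within 5 kb, kept peaks at least 1 kb wide, used covered bases, required 50% of a peak to be covered, kept the stronger 50% of each list, took equal peak numbers from all 4 lists of a mark, widened the window to 2.5 kb, or drew unmatched random lists. A few alternatives were added after seeing the data, namely whole gene records, no peak within 10 kb in the other form, and leaving out a segment of 12 Mb of chromosome 1 that starts at 150 Mb. The steps were tested on simulated data. Of 4000 simulated peaks, 2400 were made to overlap and 2400 were found, as with bedtools 2.31.1. Gene marking by simulated peaks differed from a direct loop at 0 of 500 real gene records, of which 20 were marked. In 500 random lists of 40 genes drawn from 19974, 1.2% lay outside the middle 95%, and lists with 5 planted members were above it in 100% of draws. The simulated marks were independent between genes, unlike real marks on shared peaks.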

Results

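H3K27me3, a histone mark written by Polycomb repressive complex 2 and found at silent genes, and H3K4me3, a mark of active and poised promoters, were profiled in TKO cells, a derivative of the KMS-11 multiple myeloma line with a heterozygous WHSC1 genotype in its labels. The assay was ChIPmentation, in which a transposase adds sequencing adaptors to immunoprecipitated chromatin. WHSC1 is another name of NSD2, a methyltransferase of H3K36 that the t(4;14) translocation of myeloma places under immunoglobulin control. The series asked how forms of NSD2 alter chromatin marks, and its title ties the C-terminal part of the protein to cell adhesion genes. Cells were labelled as expressing wild type NSD2 (WT), NSD2 with the substitution D1240A, NSD2 with the substitution F1295A, or as plain TKO cells, for which the labels do not name a form. Each of the 4 forms had 2 H3K27me3 samples, 1 H3K4me3 sample and 1 IgG sample, 16 samples in all. The measurements were 8 peak lists, a single list per form and mark, so both H3K27me3 replicates of a form stood in the same list and no difference below had a replicate check. The IgG samples were not analysed here, and the read depth of the samples is unknown. Intervals are exact (Clopper-Pearson) 95% intervals that cover the counting error of peaks or genes only, and neighbouring peaks and genes are not independent. A gene is called marked where a peak lay within 1 kb of either end of its record. The strand was not known, so a marked end can be the one away from the promoter.

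Across the 4 forms, 14 to 16 of 20 plasma cell identity genes carried H3K4me3 and 1 or 2 carried H3K27me3, while 12 or 13 of 39 HOX genes carried H3K27me3. IRF4, PRDM1 and XBP1, the transcription factors of the plasma cell programme, had H3K4me3 at a gene end and no H3K27me3 peak within 10 kb in every form, as did CCND2, CDKN2A, GAPDH and ACTB. NSD2 itself had H3K4me3 in every form, with 3.70 to 5.18 kb marked within 10 kb of its ends, and no H3K27me3 at its ends. The marks at NSD2 do not read the form expressed, so they do not check the labels. FGFR3, the receptor gene next to NSD2 on chromosome 4, and SDC1, which encodes the plasma cell surface protein CD138, had H3K27me3 in all 4 forms and H3K4me3 in WT and F1295A only. CD38 had no peak of either mark, and HOXA9 had none at its ends. Of 20 plasma cell identity genes, the 16 with H3K4me3 in WT stood at the 99.9th percentile of random lists matched on gene length. The 1 with H3K27me3 was inside the middle 95%. Of 20 housekeeping genes, 18 to 20 had H3K4me3 across the forms and 0 had H3K27me3.

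The H3K27me3 lists held 5881 peaks in TKO, 3790 in WT, 2188 in D1240A and 2083 in F1295A, covering 66.6, 55.7, 32.0 and 38.8 Mb. Their median widths were 7496, 9554, 10362.5 and 12792 bp in the same order. The H3K4me3 lists were closer in size, with 7396 peaks in TKO, 8140 in WT, 7712 in D1240A and 8239 in F1295A, covering 21.95, 30.2, 29.1 and 34.7 Mb. Between 71.0% and 77.6% of H3K4me3 peak centres lay within 1 kb of a gene end. Of H3K27me3 peak centres, 6.87% to 8.94% lay near a gene end, 46.2% to 53.2% inside a gene record and 38.7% to 47.0% elsewhere. The lists also differed in the weakest signal they held: the lowest 1% of peaks by mean signal ended at 9.45 in TKO and 10.3 in WT, and at 19.1 in D1240A and 18.4 in F1295A for H3K27me3. The X chromosome, with 4.25% of the 19974 genes, held 0.457% to 0.646% of the H3K27me3 peaks and 2.24% to 2.46% of the H3K4me3 peaks.

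**Figure D1:**
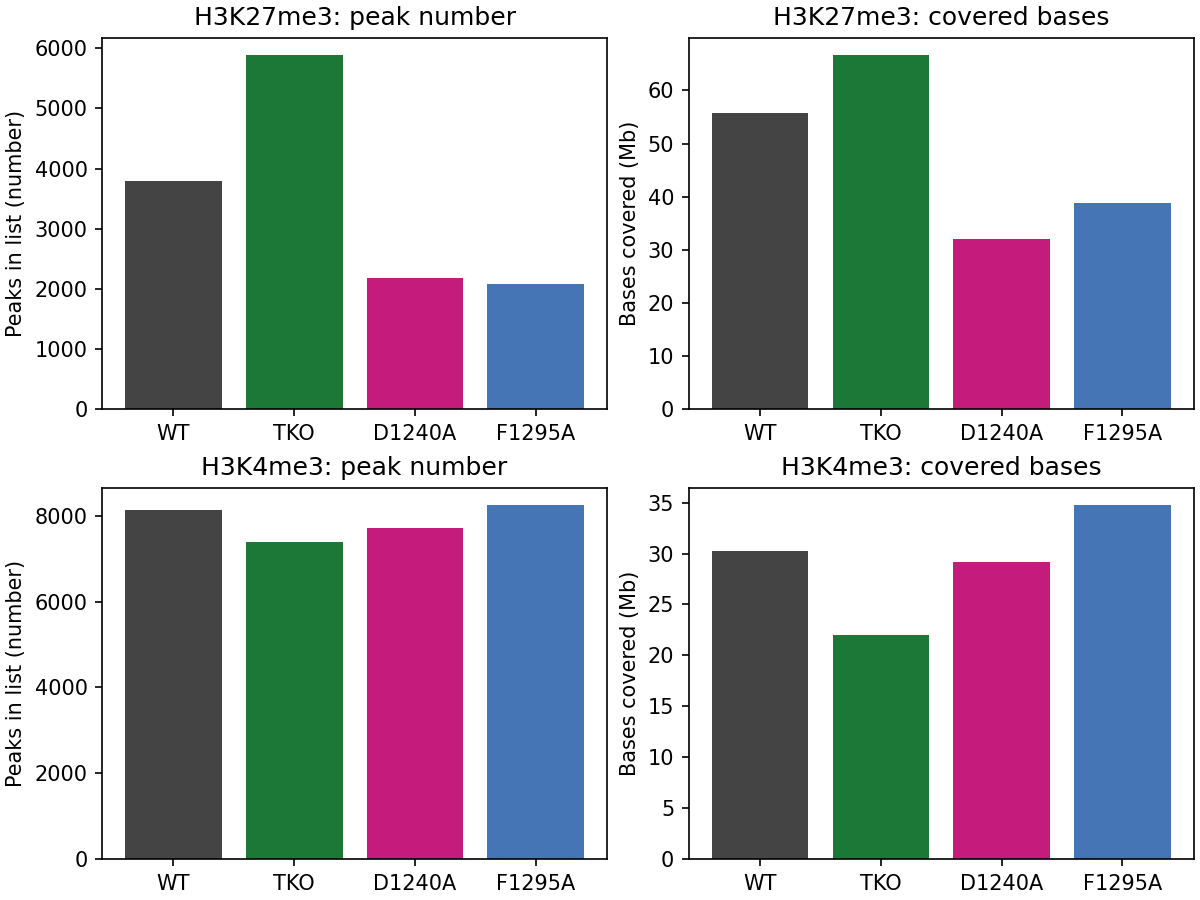
Bars give the number of peaks (left) and the bases covered in Mb (right) of each list for H3K27me3 (top) and H3K4me3 (bottom) in the 4 forms. H3K27me3 ranged from 2083 peaks in F1295A to 5881 in TKO, and H3K4me3 from 7396 in TKO to 8239 in F1295A.

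Plain TKO cells were compared with cells labelled WT to ask how the marks differ once the wild type form is expressed. H3K27me3 was in WT and not TKO at 5 of 25 B cell genes and 6 of 60 extracellular matrix genes, and in TKO and not WT at 4 of 23 markers of T, NK and myeloid cells, while most members of each list did not differ. PAX5, BCL6, SPIB, CD79B and FCER2, all genes of the B cell programme that plasma cells switch off, were marked in WT and not TKO, 5 of the 7 marked in WT against a mean of 0.447 in random lists and above all 10000 of them. Set against other genes marked in WT, the list stood at the 99.9th percentile, but inside the middle 95% with equal peak numbers (88.7th), a window of 2.5 kb (94.7th) or whole gene records (96.9th). PAX5 still had 12.3 kb of H3K27me3 within 10 kb of its ends in TKO, and CR2, another member of the B cell list, was marked in TKO and not WT. At SPIB the WT peak (50431192 to 50441841) met the record only at its higher end, 50431314, and whether that end holds the promoter was not known. The matrix genes COL7A1, COL18A1, LAMA5, HSPG2, COL2A1 and THBS3 were marked in WT and not TKO, 6 of 14 against a random mean of 0.643, and the call ended with a window of 2.5 kb (2 genes) and over whole gene records (1 gene). In the other direction CD5, CSF1R, S100A8 and FCGR3A, markers of T cells, monocytes, neutrophils and NK cells, were marked in TKO and not WT, 4 of 7 against a random mean of 0.468 (99.9th percentile), and at the 97.49th percentile among genes marked in TKO, just inside the middle 95%. The first call ended at equal peak numbers (89.7th percentile) and over whole gene records (93.7th).

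Across all genes, 434 were marked by H3K27me3 in TKO and not WT and 344 in WT and not TKO, so 55.8% (52.2 to 59.3) of the differing genes were marked in TKO. This direction depended on the length of the lists. With the 2083 strongest peaks of each list the split was 169 to 460, or 26.9% in TKO, while it was 321 to 151, or 68.0%, where the other form had no peak within 10 kb, and 614 to 306, or 66.7%, over whole gene records. TKO had 1.55 times as many H3K27me3 peaks as WT (1.49 to 1.62) and 1.196 times the covered bases. TKO peaks overlapped 89.1% of WT peaks, and WT peaks overlapped 61.6% of TKO peaks, against 6.58% and 4.55% after circular shifts.

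Adhesion genes with H3K27me3 in TKO and no peak within 10 kb in WT were few. They were PCDH12, a protocadherin of endothelium, with 8.89 kb marked within 10 kb of its ends, ITGA2, the collagen-binding integrin subunit, with 5.45 kb, and CEACAM1 with 9.57 kb. SPARC (13.0 kb), VCAN (4.78 kb) and BCAN (37.4 kb) encode matrix proteins. The other list members named by the same rule were the complement receptor gene CR2 (6.71 kb) from the B cell list, the developmental factors GATA4 (5.46 kb) and SOX21 (4.93 kb), FCGR3A (7.88 kb), CD5 (4.63 kb) and PDGFRB (5.16 kb). Adhesion and migration genes marked in WT with no peak within 10 kb in TKO were CELSR2 (6.24 kb), CADM3 (6.49 kb), ICAM4 and ICAM5 under a shared peak (5.15 kb), LAMA5 (7.31 kb) and the semaphorin receptor gene PLXND1 (7.37 kb), and BCL6 had 6.73 kb. Among all genes, IGSF9 (28.6 kb), SLAMF9 (28.4 kb), NXPH4 (19.4 kb), EVPL (18.6 kb), TNRC18 (18.0 kb), PTGDS (17.7 kb), INPP5J (17.6 kb) and CHST8 (17.6 kb) had the most marked bases in WT without a TKO peak.

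The genes with the most H3K27me3 in TKO and none in WT stood side by side on chromosome 1. A TKO peak of 157 kb at positions 156819501 to 156976875 (GRCh38) covered the insulin receptor-related gene INSRR, PEAR1 and LRRC71. A peak of 103 kb at 156610909 to 156714085 covered BCAN, the neural intermediate filament gene NES and CRABP2, which binds retinoic acid. Both peaks were among the strongest of the TKO list (99.9th and 99.8th percentile by total signal). D1240A had H3K27me3 over the same genes, and neither WT nor F1295A had a peak in these intervals. NOS1AP, also among the 8 genes with the most marked bases, lies farther along chromosome 1 and had 28.3 kb.

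**Figure D2:**
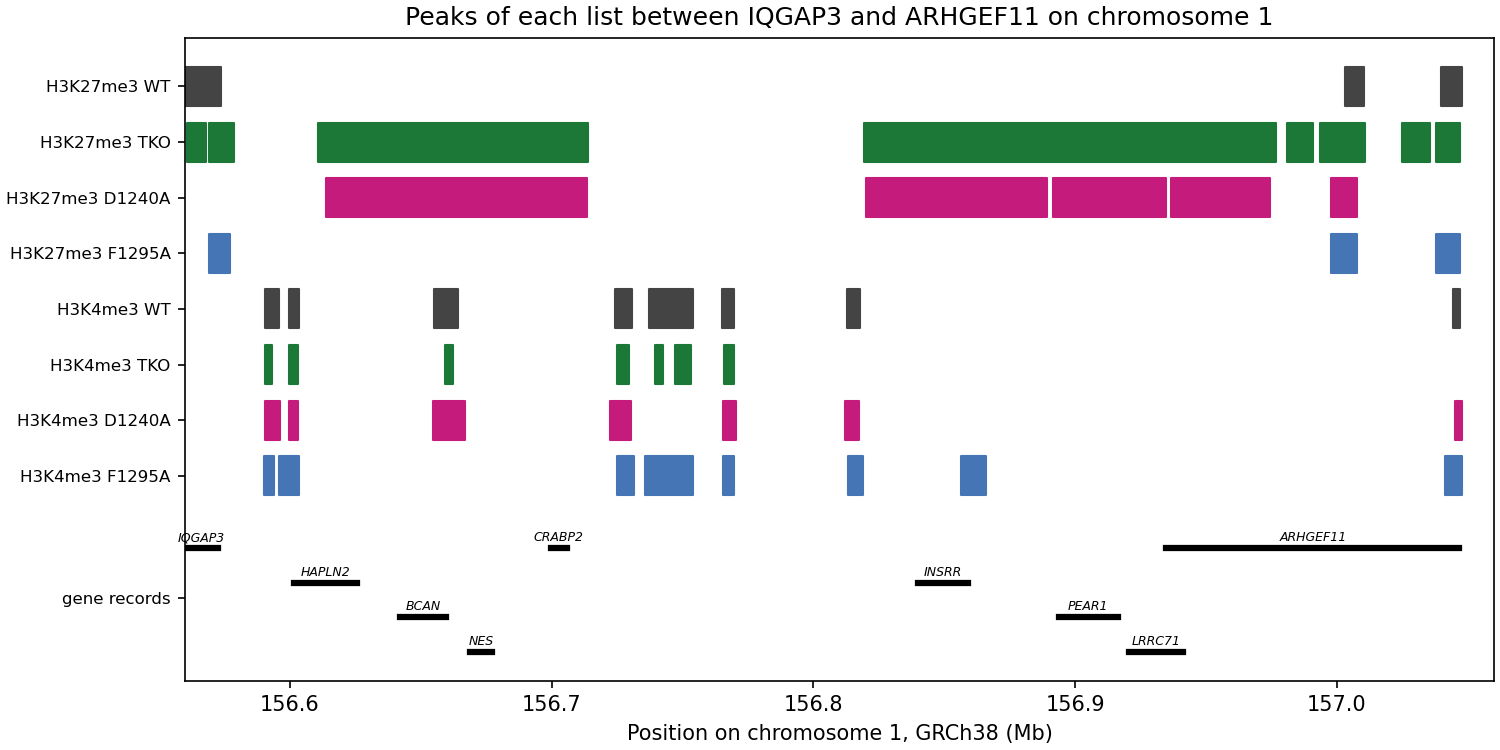
Horizontal bars show the peaks of the 8 lists along chromosome 1 (GRCh38 position in Mb), with the records of 9 genes in black at the bottom. H3K27me3 peaks of 103 and 157 kb in TKO, and peaks over the same genes in D1240A, have no counterpart in WT or F1295A.

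More genes had H3K4me3 in WT and not TKO than the reverse, and the genes without it in TKO included 4 migration receptors and 2 genes tied to t(4;14) myeloma. It was present at 817 genes in WT and not TKO and at 65 in TKO and not WT, so 7.37% (5.73 to 9.30) of the differing genes were marked in TKO, a split of 316 to 415 (43.2%) at equal peak numbers. FGFR3 (6.43 kb) and the desmosomal cadherin gene DSG2 (3.60 kb) were the 2 t(4;14) genes marked in WT only of this pair, against a random mean of 0.306 (98.2th percentile). Of 12 migration receptors with H3K4me3 in WT, 4 lacked it in TKO, namely PLXNA1, EFNB1, EPHA7 and UNC5C, against 9.34% of other marked genes (98.8th percentile among marked genes, and 93.2th among random lists, inside the middle 95%). Other members without an H3K4me3 peak within 10 kb in TKO were CELSR3, PCDH7, SELPLG, TENM4, ALCAM, F11R and AGRN among adhesion and matrix genes, POU2AF1 and SDC1 among plasma cell genes, SIX2, TBX2 and TBX3 among developmental factors (5 of 20 marked in WT, 70.7th percentile of random lists and 97.9th among marked genes), HOXD13 of the HOX list, the cell cycle inhibitor gene CDKN1C and the housekeeping gene ALAS1. They had 2.25 to 8.13 kb marked in WT, and TBX3 stood at the 0.418th percentile of the WT list by total signal and PCDH7 at the 39.7th. Among all genes the most marked bases were at SELPLG (8.13 kb), SLC9A9 (7.52 kb), SYP (7.24 kb), MC1R and TUBB3 under a shared peak (6.99 kb), HNRNPC (6.94 kb) and BMF (6.69 kb). RBBP7, a Polycomb subunit gene, PEG3, ZIM2, TTI2, KDM4B, CTBS and INPP5D had 2.93 to 3.49 kb in TKO and none in WT. TKO had 0.909 times the H3K4me3 peaks of WT (0.880 to 0.938) and 0.726 times the covered bases, and 99.1% of TKO peaks overlapped a WT peak. With WT peaks in 4 equal groups by total signal, TKO overlapped 99.9% of the strongest group and 61.1% of the weakest. The lowest 1% of peaks by mean signal ended at 26.2 in TKO and 37.5 in WT. Each list comes from 1 library of unknown depth, so a difference of depth or threshold stays open for these calls and was not tested. The H3K4me3 percentiles of gene lists given here were not recomputed at equal peak numbers or under any other alternative.

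D1240A and F1295A were each compared with WT to ask what a changed residue in the C-terminal part of NSD2 does. In both, H3K27me3 was called at far fewer genes, and the genes without a call included immunoglobulin-type adhesion molecules, matrix genes, B cell genes and all marked cell cycle genes, while 12 of the 13 HOX genes and all 6 integrins marked in WT were called in every form. Both comparisons share the WT list, so a gene marked there by chance counts in each. Of 16 immunoglobulin-type adhesion genes marked in WT, 8 were unmarked in D1240A and 7 in F1295A, at the 99.96th and 99.9th percentile of random lists. Among genes marked in WT these counts were ordinary, at the 64.8th and 56.0th percentile, since 45.3% and 41.7% of the other WT genes were unmarked too. Of the matrix list, 8 of 14 were unmarked in D1240A and 6 in F1295A (80.9th and 54.6th percentile among marked genes), and of the B cell list 5 of 7 in each (90.2th and 93.2th).

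Cell cycle and HOX genes stood at opposite ends of random draws from the genes marked in WT. These draws were not matched on peak signal. CCND1, CCND3, MYC and CDKN1A, the 4 cell cycle genes with H3K27me3 in WT, were unmarked in both mutants (97.8th percentile among marked genes for D1240A and 98.5th for F1295A). Of 13 marked HOX genes only HOXB13 was unmarked in each mutant (0.230th and 0.460th percentile), while HOXB6, HOXB8, HOXB9 and 9 genes of the HOXC cluster were marked in every form under few shared peaks. ITGA3, ITGA5, ITGA7, ITGA10, ITGB2 and ITGB4 were marked in every form, so 0 of 6 were unmarked in a mutant (1.44th and 1.78th percentile). At equal peak numbers the integrins stood at the 4.70th and 7.79th percentile and the HOX genes at the 2.53th and 6.37th, inside the middle 95% of random draws.

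Members named for both mutants, marked in WT with no H3K27me3 peak within 10 kb in either, were the cadherin genes CDH4 (9.08 kb) and CELSR2, the neural adhesion gene L1CAM (28.3 kb), CADM3, MCAM (5.88 kb), the laminin genes LAMB3 (16.3 kb) and LAMA5, the cartilage proteoglycan gene ACAN (6.04 kb), SEMA7A (10.6 kb), PLXND1, SPIB (10.1 kb), BCL6, TAL1 (15.7 kb), DLX1 (13.5 kb), DLX2 (11.9 kb), NEUROG3 (9.56 kb), CCND1 (13.7 kb), CCND3 (5.15 kb) and MYC (4.63 kb). CDH4 and ACAN had a peak elsewhere in their records in both, as did PAX5 in D1240A and HSPG2 in F1295A. For D1240A alone the rule added F11R (5.86 kb), PAX5 (24.0 kb), HOXB13 (12.6 kb) and MPO (18.7 kb), and for F1295A alone NECTIN2 (10.3 kb), HSPG2 (14.1 kb) and CDKN1A (6.04 kb). Among all genes, IGSF9 and L1CAM were among the 8 with the most bases for both mutants. ZDHHC1 (29.7 kb), CREB3L3 (27.5 kb), CARD10 (26.9 kb), DRC4 (26.3 kb) and DISP2 (25.4 kb) were further members of the group for D1240A, and SLC22A8 (27.02 kb), THEM5 (25.1 kb), SPATC1 (23.8 kb), ATAD3C (23.8 kb) and SLC13A2 (23.1 kb) that for F1295A.

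D1240A marked 26 genes that WT did not and WT marked 866 that D1240A did not (2.91% in D1240A, 1.91 to 4.24), and for F1295A the counts were 42 and 797 (5.01%, 3.63 to 6.71). At equal peak numbers the shares were 14.3% and 21.99%. Genes marked in D1240A and not WT were led by those of the chromosome 1 interval, INSRR (39.1 kb), LRRC71 (38.4 kb), PEAR1 (37.7 kb), BCAN (37.4 kb), NES (28.6 kb) and CRABP2 (24.1 kb), with RIIAD1 (31.5 kb) from another part of the chromosome. Those of F1295A were RIIAD1 (36.4 kb) and CELF3 (23.4 kb) under a shared peak, GTSF1 (13.7 kb), BATF3 (11.6 kb), STAC3 (10.9 kb), OR10P1 (10.7 kb), PDE4DIP (9.65 kb) and CRIP2 (9.17 kb).

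Most H3K27me3 peaks of the mutants touched a WT peak. WT peaks overlapped 98.3% of D1240A peaks and 96.3% of F1295A peaks by at least 1 bp, and held 94.5% and 90.3% of their bases, while D1240A overlapped 49.3% of WT peaks and F1295A 53.0%. Peak numbers were 0.577 (0.547 to 0.609) and 0.550 (0.521 to 0.580) of WT, and covered bases 0.575 and 0.698. With WT peaks in 4 equal groups by total signal, D1240A overlapped 95.7% of the strongest group and 8.66% of the weakest, and F1295A 95.4% and 13.7%. The lowest 1% of peaks by mean signal ended near 19.1 and 18.4 in the mutants against 10.3 in WT, as given above.

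**Figure D3:**
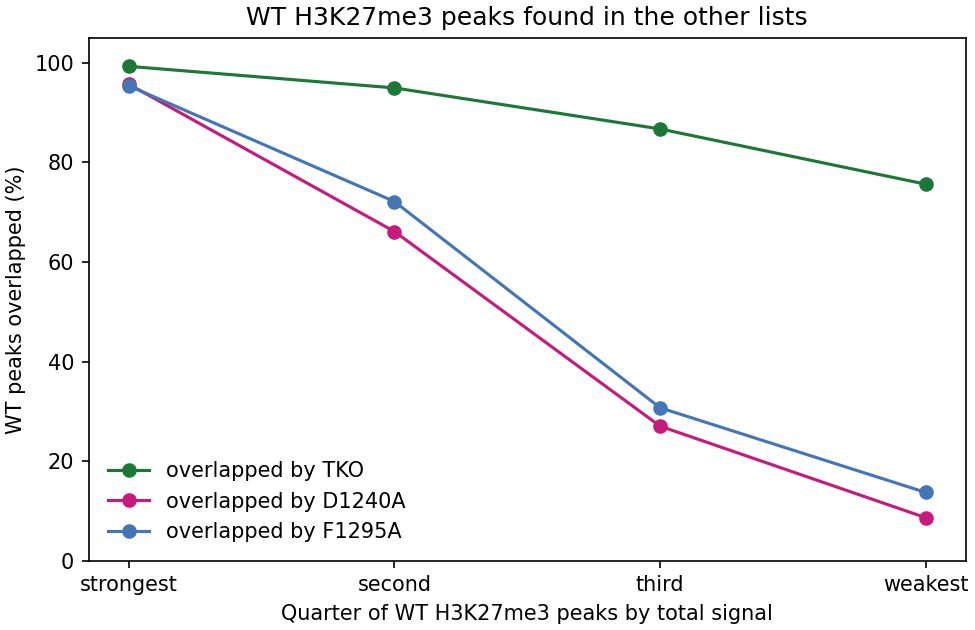
Points give the percent of WT H3K27me3 peaks overlapped by the list of each other form, for WT peaks in 4 equal groups by total signal from the strongest to the weakest. Overlap by D1240A fell from 95.7% to 8.66% and by F1295A from 95.4% to 13.7%.

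H3K4me3 differed from WT in opposite directions in the mutants. Of the genes that differed, D1240A marked 57 and WT 459, or 11.05% in D1240A (8.48 to 14.1), while F1295A marked 317 and WT 143, or 68.9% in F1295A (64.5 to 73.1). At equal peak numbers the shares were 45.2% and 58.6%. FGFR3, SDC1, PCDH7, TENM4, F11R, UNC5C, HOXD13, SIX2, TBX2, the lung and thyroid factor gene NKX2-1, CDKN1C and ALAS1 had H3K4me3 in WT and no peak within 10 kb in D1240A. Of the 20 developmental factors marked in WT, 4 were unmarked in D1240A (82.9th percentile of random lists and 98.8th among marked genes). Neither percentile was recomputed at equal peak numbers. Across all genes, ADAMTSL4 (11.6 kb), EFNA3 (10.5 kb), MC1R and TUBB3, FGFR3 and ALG1L2 (5.77 kb) led this group. EFNA3, MC1R, TUBB3 and ALG1L2 were unmarked in F1295A as well, and the EFNA3 peak stood at the 95.6th percentile of the WT list by total signal. D1240A had H3K4me3 without WT at CDH24 (2.96 kb), the potassium channel gene KCNH2 (9.92 kb), EVC and EVC2 under a shared peak (6.48 kb), the Notch ligand gene DLL4 (5.57 kb), MAST1, TTI2, ELAVL2 and KDM4B.

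F1295A had H3K4me3 without WT at CDH24 (4.35 kb), the laminin gene LAMB2 (3.41 kb), SERPINE2 (2.57 kb), HOXA10 (5.22 kb), OLIG1 (2.60 kb) and RBBP7 (3.11 kb). Among all genes the most marked bases were at INSRR (9.85 kb), KCNH2 (8.28 kb), MAST1 and PLXNB2 (7.48 kb each), ATP2A1 (6.503 kb), DLL4 (6.22 kb) and ARMC12 and FKBP5 under a shared peak (6.17 kb). WT had H3K4me3 without F1295A at BCAN (9.10 kb), AGRN (4.67 kb), UNC5C (2.07 kb), NKX2-1 (3.42 kb), EFNA3, MC1R, TUBB3, and IGSF9 and TAGLN2 under a shared peak (4.40 kb). H3K4me3 peak numbers were 0.947 (0.918 to 0.978) of WT in D1240A and 1.01 (0.982 to 1.04) in F1295A, and covered bases 0.964 and 1.15. D1240A overlapped 94.2% of WT peaks and F1295A 98.3%.

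D1240A and F1295A were compared with each other to separate the 2 substitutions. Their H3K27me3 lists were close in size, 1.05 times as many peaks in D1240A (0.989 to 1.12) with 0.824 times the covered bases. The clearest difference was the chromosome 1 interval, where INSRR, LRRC71, PEAR1, BCAN, NES, CRABP2 and HAPLN2 (20.0 kb) were marked in D1240A and had no peak within 10 kb in F1295A. NECTIN2 (9.46 kb) and the kidney factor gene LHX1 (9.02 kb) were also marked in D1240A. F1295A marked the myeloid peroxidase gene MPO (10.6 kb), DISP2 (25.04 kb), DRC4 (24.3 kb), FCAMR (24.1 kb), TMEM275 (23.4 kb), DPYSL5 (23.001 kb), ADAMTS14 (22.3 kb), KRT82 (20.3 kb) and PDE1B (19.2 kb). In all, 120 genes were marked in D1240A only of this pair and 205 in F1295A only (36.9% in D1240A, 31.7 to 42.4). F1295A overlapped 89.5% of D1240A peaks and D1240A 82.1% of F1295A peaks.

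H3K4me3 was present at 624 genes in F1295A and not D1240A and at 48 in the reverse (7.14% in D1240A, 5.31 to 9.36, and 36.6% at equal peak numbers). FGFR3 (11.2 kb) and SERPINE2, both tied to t(4;14) myeloma, were marked in F1295A against a random mean of 0.219 (98.9th percentile). Of 22 developmental factors with H3K4me3 in F1295A, 6 lacked it in D1240A, against 6.97% of other marked genes (99.8th percentile among marked genes, and 83.9th among random lists, inside the middle 95%). TBX2, SIX2 and OLIG1 were among the members, with HOXA10, HOXD12 and HOXD13 from the HOX clusters. PCDH7, TENM4, F11R, LAMB2, SDC1, CDKN1C, RBBP7, POLR2A and ALAS1 were other list members. ADAMTSL4 (22.9 kb), under an F1295A peak of 33.2 kb at the 99.9th percentile of its list, INSRR, TNFRSF10B (8.80 kb), FOXO6 (8.79 kb), PLXNB2 and TSPYL2 (7.12 kb) led among all genes. D1240A had H3K4me3 without F1295A at the matrix genes BCAN (12.1 kb) and AGRN (10.4 kb), against a random mean of 0.153 for the list (99.5th percentile), and at EVC, EVC2, ADAMTS6 (4.28 kb), ELAVL2 and ZFX. D1240A had 0.936 times the H3K4me3 peaks of F1295A (0.907 to 0.966). The percentiles of gene lists in this comparison were not recomputed at equal peak numbers.

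The adhesion families differed in how often they carried H3K27me3 in WT. It marked 16 of 63 immunoglobulin-type adhesion genes (random mean 4.66), 14 of 60 matrix genes (4.24), 10 of 39 migration receptors (3.24) and 6 of 26 integrins (2.01). Each stood above the 99.1th percentile of random lists, which were matched on gene length and not on CpG content. It marked 6 of 43 cadherins (95.8th percentile), 1 of 12 non-clustered protocadherins and 0 of 53 clustered protocadherins, which also had no H3K4me3 in any form. NFASC, NECTIN4, BCAM, CNTN2, CD44, KIRREL2 and TENM4 were marked in all 4 forms, as were CDH15, CDH16, CDH22 and CDH23, COL1A1, COL5A1, LAMC3, TNXB, FBLN2 and AGRN, and CXCR5, CCR7, UNC5A, UNC5B, EPHA2, EPHB2, EPHB4 and EFNA1. These names were chosen after their values were seen, because they complete the lists. WT marked 20 of 127 developmental factors, 3 of 29 Polycomb and H3K36 or H3K27 regulators, 4 of 20 cell cycle genes, 3 of 23 T, NK and myeloid markers, 3 of 21 stromal, endothelial and erythroid markers and 1 of 7 t(4;14) genes with H3K27me3, all inside the middle 95% of random lists. In other forms some lists stood above it, namely T, NK and myeloid markers in TKO (7 of 23, 99.6th percentile), developmental factors in D1240A (15 of 127, 99.2th), and cadherins (5 of 43, 98.2th) and stromal, endothelial and erythroid markers (4 of 21, 98.2th) in F1295A.

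**Figure D4:**
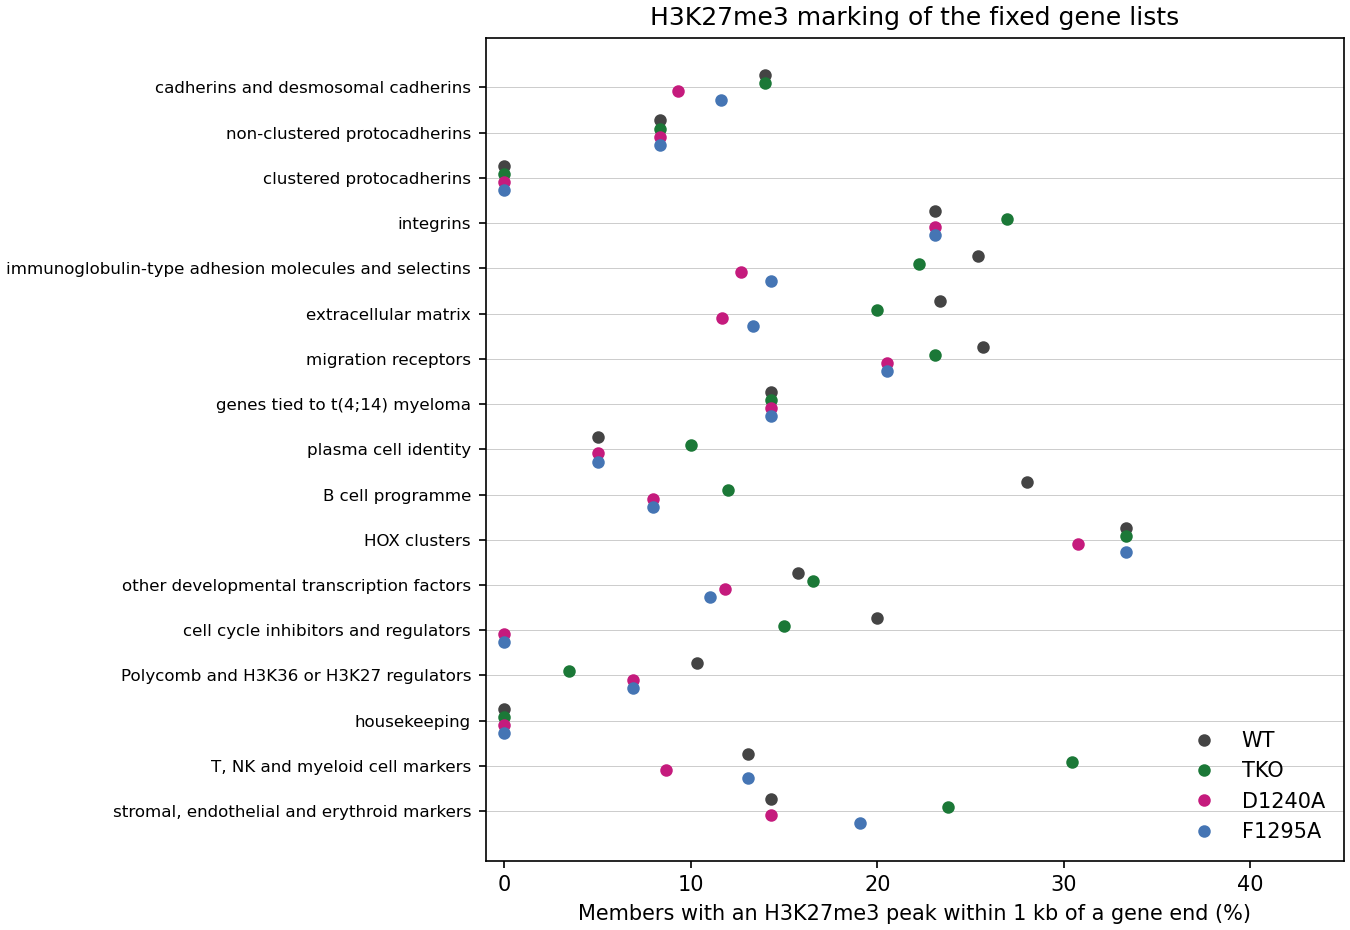
Points give the percent of members of each gene list with an H3K27me3 peak within 1 kb of a gene end, for the 4 forms. The B cell programme had 28.0% in WT against 8.0% in both mutants, and the HOX clusters had 30.8% to 33.3% in every form.

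Genes with both marks were a minority of the H3K27me3 genes in each form. Each mark was read at either gene end, so the marks of such a gene can lie at different ends and need not share a promoter. They numbered 318 of 1911 in WT (16.6%, 14.997 to 18.4), 223 of 2001 in TKO (11.1%, 9.80 to 12.6), 145 of 1071 in D1240A (13.5%, 11.6 to 15.7) and 194 of 1156 in F1295A (16.8%, 14.7 to 19.1), while 43.6% of all genes had H3K4me3 in WT. With the stronger 50% of each list the shares were 4.98% to 7.02%. FGFR3, SDC1 and TENM4 had both marks by this reading in WT and F1295A, and ICAM4, ICAM5 and LAMA5 in WT. The H3K27me3 peak of ICAM4 in WT began at 10288899, beyond the end of its record at 10288520. H3K27me3 was present in all 4 forms at 923 genes and H3K4me3 at 7782.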

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

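The tests of weak and strong peaks, of chance placement, of DNA copies and of DNA loss beyond the first reading of the widest chromosome 1 block were chosen only after the result was seen, as was the reading of covered bases as a test of joined peaks, while covered bases and equal peak numbers themselves were planned. H3K4me3 calls went opposite ways from WT in the 2 mutants, with 11.05% of differing genes marked in D1240A and 68.9% in F1295A, and the difference between these shares was not tested. Each value rests on 1 library per form. Depth or threshold differences between these libraries fit the values, since 97.9% of the WT peaks absent from D1240A (465 of 475) and 98.0% of the F1295A peaks absent from WT (297 of 303) were in the weakest of 4 equal groups by total signal. Equal peak numbers brought the shares to 45.2% and 58.6%, closer together and still on opposite sides of an even split. A difference between the NSD2 forms stays open as well, untested for want of replicates.

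The mutant H3K27me3 lists held fewer peaks than the WT list. Joining of neighbouring peaks into wider ones was excluded as the whole cause, because covered bases were at most 0.698 of WT in either mutant. A stricter effective threshold or lower depth may account for the pattern, since both mutants overlapped at least 95.4% of the strongest group of WT peaks and missed mostly weak ones. A lower level of H3K27me3 under the mutant forms would also remove weak peaks first, so it stays open and was not tested. The lowest 1% of peaks by mean signal ended at 19.1 in D1240A and 18.4 in F1295A against 10.3 in WT. If the signal is unscaled, this goes with a stricter threshold more than with lower depth, but its scaling is unknown.

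Strong H3K27me3 peaks present in some forms and absent from others crowded on chromosome 1 in a segment of 12 Mb that starts at 150 Mb, where 8 of 12 strong blocks were one-sided, against 43 of 296 in the genome. Among random draws of strong blocks, 8 blocks in 12 Mb stood at the 99.9th percentile (random mean 3.97, highest 8). With the best of 5 window widths the percentile was the 99.7th. The crowding was seen in these same peaks first. The draws treat blocks as interchangeable, although those over BCAN and INSRR lie side by side and counted separately because they are over 100 kb apart. H3K4me3 signal in the segment also differed from elsewhere, as given below. The draws therefore cannot decide on chance placement. More DNA copies of the whole segment in D1240A were read as at least 1.5 times the WT H3K4me3 signal, each relative to peaks elsewhere. The ratio was 0.992 (0.951 to 1.05) over 110 shared peaks, which excluded such a gain across the segment. A gain limited to the widest blocks, which held at most 1 H3K4me3 peak per form, was not addressed. TKO over WT gave 1.19 (1.13 to 1.23), so a smaller difference in copies, or another cause of higher signal, stays open for TKO. In every form the segment had more H3K4me3 signal than peaks elsewhere, from 1.41 times in F1295A to 1.96 times in TKO. The first reading of DNA loss, H3K4me3 peaks in the widest block, gave 0 in WT, which decides nothing for WT since TKO and D1240A also had 0, and 1 in F1295A, which excludes complete loss of that block there. Tests added after that outcome covered the 4 blocks strong in TKO or D1240A and absent from WT and F1295A. They found 1 H3K4me3 peak in WT, in the BCAN block, and 1 in F1295A. Complete loss of the BCAN block in WT, and of all 4 blocks in either form, is therefore excluded. F1295A had 0 H3K4me3 peaks in the BCAN block, where WT, TKO and D1240A each had 1. Complete loss of the BCAN block in F1295A therefore stays open. Loss of part of a block, of some of its copies or of the other blocks in each form may underlie the pattern and stays open. A clonal difference and the NSD2 form stay open as well. RIIAD1, CELF3, IGSF9, SLAMF9, CADM3, F11R and FCGR3A, named above for H3K27me3 differences, also lie in the segment. The same causes stay open for their calls.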

How the results depend on the processing

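Whole gene records, the absence of peaks within 10 kb in the other form and the omission of part of chromosome 1 were chosen only after the data were seen. No paired analysis was possible because the results come from no test and both replicates of a form stood in 1 list, and for the same reason no replicate could be left out. The alternative of any annotated transcription start site was not run, since the gene table used here has none. Of 327 values recomputed for 85 results, 214 stayed the same, 85 moved, 27 fell inside the middle 95% of random lists and 1 reversed. Percentiles of gene lists with H3K4me3 in a single form of a pair were not among these results, so how they depend on the processing is unknown. Values counted as the same lay within their counting interval or on their side of that middle. Counts of differing genes, which have no interval, counted as the same within a fixed fold of the main count. Except where an alternative shortens the lists or widens the window by construction, the cause was not tested. Depth is unknown and limits every comparison of list lengths. Peaks at least 1 kb wide and leaving out the 12 Mb of chromosome 1 that start at 150 Mb left all 8 ratios of peak numbers within their intervals.

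Joining peaks within 5 kb moved the H3K27me3 ratio to 1.48 for TKO over WT and 0.584 for F1295A over WT. Covered bases gave H3K27me3 ratios of 1.196 for TKO over WT, 0.698 for F1295A over WT and 0.824 for D1240A over F1295A, and H3K4me3 ratios of 0.726, 1.15 and 0.840 for the same pairs.

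With 50% of a peak covered, H3K27me3 overlap was 85.3% of WT by TKO, 58.5% of TKO by WT, 97.3% of D1240A by WT, 43.0% of WT by D1240A, 93.6% of F1295A by WT, 49.4% of WT by F1295A and 76.0% of F1295A by D1240A. For H3K4me3 it was 87.2% of WT by TKO, 99.1% of D1240A by WT, 94.8% of F1295A by WT and 91.1% of F1295A by D1240A.

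With the stronger 50% of each list, H3K27me3 overlap was 86.4% of WT by TKO, 62.9% of TKO by WT, 96.3% of D1240A by WT, 45.1% of WT by D1240A, 51.1% of WT by F1295A, 91.2% of D1240A by F1295A and 78.3% of F1295A by D1240A. H3K4me3 overlap was 86.4% of WT by TKO, 95.9% of TKO by WT, 97.9% of D1240A by WT, 92.7% of WT by D1240A, 93.6% of F1295A by WT, 95.5% of WT by F1295A, 97.6% of D1240A by F1295A and 90.5% of F1295A by D1240A. The share of differing genes marked in the first form was 3.45% for H3K27me3 in F1295A against WT and 30.6% in D1240A against F1295A (206 genes differing against 325). For H3K4me3 it was 21.3% in TKO, 23.1% in D1240A and 61.8% in F1295A against WT, and 18.8% in D1240A against F1295A. Both marks were at 6.90% of H3K27me3 genes in WT, 4.98% in TKO, 5.87% in D1240A and 7.02% in F1295A.

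At equal peak numbers, H3K27me3 overlap was 70.9% of WT by TKO, 78.4% of TKO by WT, 88.4% of D1240A by WT, 75.4% of WT by D1240A, 82.6% of F1295A by WT, 80.0% of WT by F1295A and 79.5% of F1295A by D1240A. H3K4me3 overlap was 94.6% of WT by TKO, 95.5% of TKO by WT, 97.3% of D1240A by WT, 97.2% of WT by D1240A, 97.2% of WT by F1295A, 97.54% of D1240A by F1295A and 96.7% of F1295A by D1240A. The share of differing H3K27me3 genes reversed to 26.9% in TKO against WT, and was 14.3% in D1240A (533 genes differing against 892) and 21.99% in F1295A (482 against 839). For H3K4me3 the shares were 43.2% in TKO, 45.2% in D1240A and 58.6% in F1295A against WT, and 36.6% in D1240A against F1295A. The T, NK and myeloid list in TKO and not WT fell to the 89.7th percentile, and clustered protocadherins with H3K27me3 in WT rose to the 2.85th. Among marked genes, integrins in WT and not the mutants stood at the 4.70th (D1240A) and 7.79th (F1295A) percentile and HOX genes at the 2.53th and 6.37th. HOX genes in TKO and not WT stood at the 5.91th, and matrix and B cell genes in WT and not TKO at the 96.3th and 88.7th.

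Over whole gene records, 66.7% of differing H3K27me3 genes were marked in TKO against WT, and both marks were at 20.3% of H3K27me3 genes in WT, 15.1% in TKO, 16.0% in D1240A and 20.0% in F1295A. Matrix genes with H3K27me3 in WT stood at the 74.0th percentile against TKO, 68.0th against D1240A and 95.6th against F1295A, and B cell genes at the 92.8th against D1240A and 93.8th against F1295A. The T, NK and myeloid list in TKO and not WT stood at the 93.7th. Among marked genes, integrins stood at the 12.7th (D1240A) and 15.7th (F1295A), and matrix and B cell genes in WT and not TKO at the 15.2th and 96.9th.

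Where the other form had no peak within 10 kb, the H3K27me3 share was 68.0% in TKO (472 genes differing against 778) and 1.64% in F1295A against WT, and 44.0% in D1240A against F1295A (191 against 325). The H3K4me3 share was 5.65% in D1240A and 62.7% in F1295A against WT (295 against 460 for F1295A), and 5.09% in D1240A against F1295A.

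With a window of 2.5 kb, both marks were at 21.8% of H3K27me3 genes in WT, 16.1% in TKO, 18.2% in D1240A and 21.6% in F1295A. Matrix genes with H3K27me3 in WT stood at the 91.9th percentile against TKO, 96.2th against D1240A and 96.6th against F1295A, and B cell genes at the 92.8th against F1295A. Among marked genes, matrix and B cell genes in WT and not TKO stood at the 44.2th and 94.7th, and HOX genes with H3K4me3 in WT rose to the 9.38th. Random lists not matched on length put immunoglobulin-type adhesion genes in WT and not TKO at the 94.2th.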

Other observations

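The test of H3K4me3 calls in this part was chosen after the result was seen. Genes whose marks differed in opposite ways between 2 forms were uneven by pair. In TKO against WT, 29 genes had H3K27me3 in TKO only and H3K4me3 in WT only, among them NOS1AP, BATF3, CRIP2 and the growth factor gene TGFA, while 4 genes, ARID3C, DDT, DLX2 and KCNH4, had the reverse. In F1295A against WT, 29 genes had H3K27me3 in WT only and H3K4me3 in F1295A only, among them BCL6, DLX2, CDHR4 and LY6E, and 0 had the reverse. D1240A against WT gave 2 such genes, KCNH4 and NPAS1, and D1240A against F1295A gave 7, CCDC136, EXTL1, IMPDH1, INSRR, LRP2, PRDM12 and PSCA. All of these examples were chosen after their values were seen, and all counts move with the length of the lists.

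The hypothesis that an H3K27me3 call that appears goes with a lost H3K4me3 call was left undecided, and its comparisons and bounds were set after the values were seen. Of genes with H3K4me3 in WT, 31.5% (29 of 92) lacked it in TKO where H3K27me3 was in TKO only, and 29.6% (67 of 226) where H3K27me3 was in both forms, a difference of 1.88 percentage points (-8.75 to 13.4, counting error only). The share was 16.3% (15 of 92) where H3K27me3 was in WT only and 8.50% (706 of 8303) where it was in neither form, lower than in the first group by 15.2 points (2.87 to 27.03) and 23.02 points (14.4 to 33.1). The share was thus higher in both groups with H3K27me3 in TKO than in the groups without it. These groups were not matched on H3K4me3 signal. TKO overlapped 99.9% of the strongest of 4 equal groups of WT H3K4me3 peaks and 61.1% of the weakest, so peak strength may account for the contrast and was not tested.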
